A study of Mus musculus with 16 samples.

How the data were processed

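RNA of sorted olfactory mucosa cells was measured on 16 Clariom S arrays from C57BL/6 mice of both sexes, 7 to 12 weeks old. Per the labels, 24 mice stayed singly in clean air chambers for 40 h at 3.1 L/min, received odorant or vehicle for 10 s every 20 min from 26 h on, and gave 50 to 100 ng of RNA per sample. The deposited values are log2 probe set summaries made by the authors with Affymetrix Expression Console, per the submitters' processing notes; the summary algorithm, its version and the annotation build are not given in the sources used here. The values ran from 1.44 to 19.7. Depth is not defined for arrays, and the number of arrays limits the precision.

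Of 28846 rows, 6640 control rows (6546 negative controls, 63 ERCC and 31 AFFX rows) were left out and 22206 probe sets were tested. The platform annotation gave 19572 probe sets 1 gene and 2634 none, and none had several. All 19572 matched the RefSeq gene table of assembly GRCm38.p6 by gene identifier, and 0 symbols changed; since the build of the array annotation is not named, no coordinates are given. Where a gene had several probe sets (55 genes), the one with the highest mean was named. Odorant receptors were the 1091 probe sets with an Olfr symbol, including 7 pseudogenes. The background level, log2 4.802, was the 95th percentile of group means over 356 probe sets of vomeronasal and bitter receptors. A lower group mean is called below background. Probe sets of close receptor paralogs can share signal, so values of single receptors are uncertain where sequences are near identical.

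Groups followed the titles. One linear model of 4 group means was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a block, and 5 contrasts were taken: undecanal minus vehicle in each fraction, titled GFP+ minus titled GFP- in each agent, and the interaction. P-values were adjusted by Benjamini-Hochberg over all probe sets, and for receptors also over the list alone, with a threshold of 0.05. 23 gene lists and 3 gene families were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. Comparisons, lists, named genes and most alternatives were fixed before the data were examined, and the text names part of the genes the rule gave. For the undecanal effect in titled GFP+ and the interaction the rule took up to 12 highest and 5 lowest receptors passing over the list alone, and up to 6 highest and 6 lowest other genes passing over all probe sets. For titled GFP- it took up to 5 per direction of each kind. Between fractions of vehicle pools it took up to 10 per direction over all genes and up to 5 per direction among receptors, with the values of the same genes in undecanal pools. Where nothing passed it took the 5 smallest p, from each list up to 4 passing members by size or else the 2 smallest p, and S100a5 and Omp always.

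The labels' 24 mice in groups of 3 make 8 pools, so same-numbered arrays of 1 agent are taken as fractions of the same mice. Deviations from group means of such pairs correlated with r from 0.050 to 0.271, over 0.1 in 6 of 8 pools, and 7 of 8 arrays titled GFP+ correlated best with their own pool. The same number under different agents gave r from -0.042 to 0.291 and does not pair mice. Arrays correlated with r from 0.989 to 0.993 within groups and from 0.953 to 0.975 between fractions, and 0 pairs of arrays held identical values.

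The tests were checked over 20 simulations, with 200 changed genes of the 22206 or of the 1091 receptors. Each probe set had its mean over the groups and its measured spread within groups. The simulated noise was independent between arrays, without pairs of fractions or differences by pool number, so the shares below need not hold for the real arrays. For undecanal in titled GFP+ 65.6% of changes of 1 and 97.6% of changes of 2 on the log2 scale were called over 22206 probe sets, and 53.4% and 94.7% among 1091 receptors. The interaction recovered 32.4% and 86.0% over 22206 probe sets, and 25.9% and 76.3% among 1091 receptors. Of the simulated receptor calls 7.21% to 8.91% were false, above the 5% aimed for, and with no change the interaction called 0.35 receptors per simulation on average. Alternatives covered scaling, filters on dim probe sets, the prior variance, array weights, replicate blocks, left-out pools and the adjustment.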

Results

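The series measured mRNA in sorted cells of the mouse olfactory mucosa, the nasal tissue that holds the olfactory sensory neurons. The mice carried a green fluorescent protein (GFP) fused to tau and driven from S100a5, a gene whose transcription in these neurons depends on their activity. Mice were exposed to undecanal, a fatty aldehyde odorant, or to filtered air as vehicle, and the dissociated mucosa was sorted on GFP. Clariom S arrays were hybridised for 4 pools of 3 mice per agent, with 2 sort fractions per pool, which gave 16 arrays in 4 groups of 4. Each neuron expresses mainly 1 odorant receptor gene, so receptor mRNA that is enriched among GFP-bearing cells after an odorant marks receptors of responding neurons, and this is the question the assay addresses. The arrays held 1091 odorant receptor probe sets, of which 1011 lay above a background level of log2 4.802 in at least 1 group. The number of arrays limits the precision. The p-values of the main fit rest on the spread between arrays within groups and treat the 2 fractions of a pool as independent.

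The titles and the sample characteristics gave opposite GFP signs in all 16 samples, so the fractions are called titled GFP+ and titled GFP- throughout. S100a5, the gene that drives the reporter, was lower in the array titled GFP+ of 8 of 8 pools. The difference, titled GFP+ minus titled GFP-, was -0.91 on the log2 scale (SE 0.167, limma adjusted p = 7.15e-04) in vehicle pools and -0.97 (SE 0.167, limma adjusted p = 3.94e-04) in undecanal pools. S100a5 averaged 16.58 ± 0.26 (SD, n = 4) in vehicle arrays titled GFP- and 15.66 ± 0.126 (SD, n = 4) in those titled GFP+. Other genes that rise with activity in olfactory neurons went the same way, among them Pcp4l1 (-1.71 in vehicle pools), Lrrc3b (-1.88) and the adhesion molecules Pcdh10 (-1.46) and Kirrel2 (-1.16). The Kirrel2 call was lost with mature neuron list centring, with only the groups compared in the fit and without vehicle pool 1 or 2 or undecanal pool 3, with limma adjusted p up to 0.14. Omp, a marker of mature olfactory neurons, differed by -0.0035 (SE 0.11) in vehicle pools. With arrays centred on their median Omp passed as lower, by -0.36 in vehicle pools (limma adjusted p = 0.0133) and -0.40 in undecanal pools (limma adjusted p = 0.00812), so its level between fractions depended on the scaling. The values of S100a5 therefore go with the characteristics and against the titles, and every direction below is that of the arrays as titled. If the characteristics are right, the arrays titled GFP- held the GFP-bearing cells and are the ones that address the question of the assay. Each difference between fractions, and the interaction, would then turn sign, while an undecanal effect within a fraction would keep its sign.

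**Figure D1:**
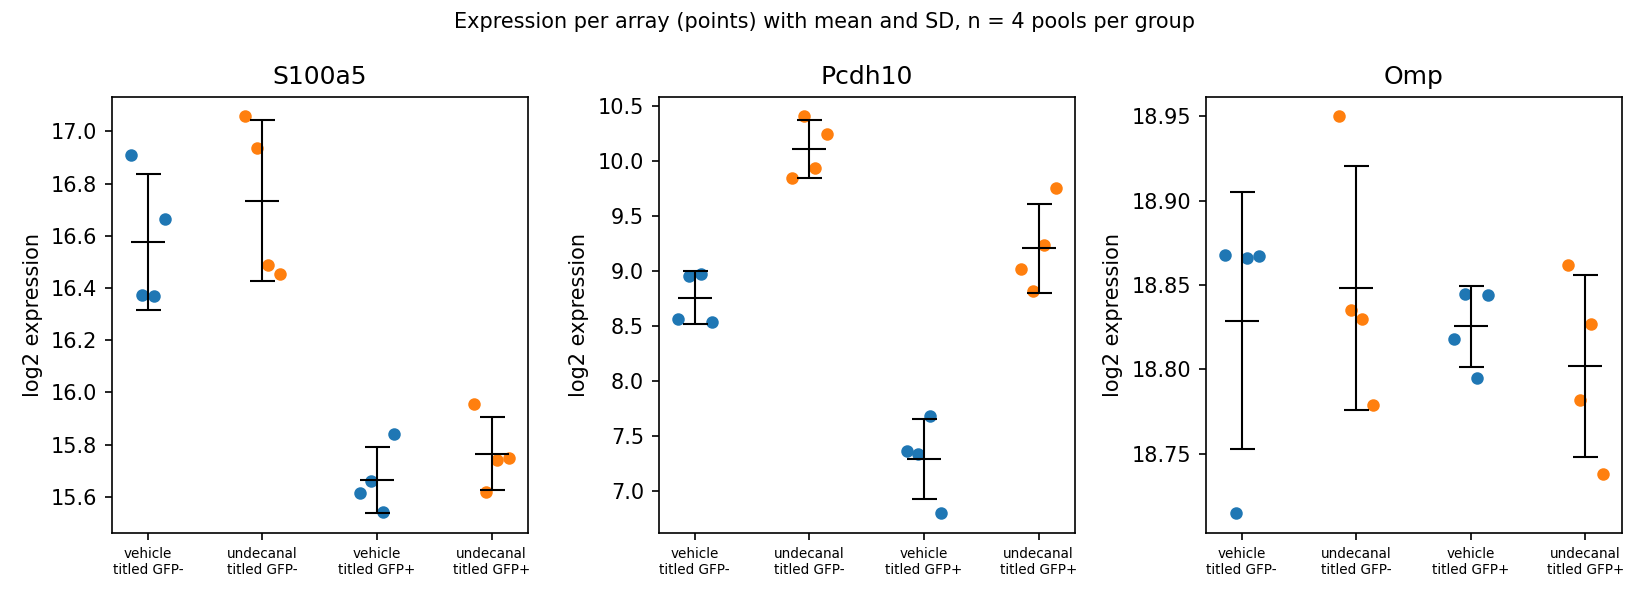
Log2 expression of S100a5, Pcdh10 and Omp in each array (points, blue vehicle and orange undecanal), with the mean and SD of 4 pools per group; the axes do not start at 0. S100a5 averaged 15.66 and 15.77 in the groups titled GFP+ against 16.58 and 16.73 in those titled GFP-, and Pcdh10 was higher with undecanal in both fractions.

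In arrays titled GFP+, Pcdh10, a protocadherin that acts in the sorting of olfactory axons, was higher with undecanal by 1.91 on the log2 scale (SE 0.218, limma adjusted p = 2.05e-03). Its mean went from 7.294 ± 0.363 (SD, n = 4) with vehicle to 9.206 ± 0.403 (SD, n = 4) with undecanal, a 3.76-fold difference, and all 4 undecanal arrays lay above all 4 vehicle arrays. It was the 1 probe set of 22206 that passed, and 603 had an unadjusted p under 0.05 where chance gives 1110. Counts under the chance value, here and below, do not show that effects were absent, and their cause was not tested. None of the 1091 odorant receptors passed in limma, adjusted over the list alone or over all genes, and 39 had an unadjusted p under 0.05 where chance gives 54.55. The 5 receptors with the smallest p did not pass: Olfr1 (-0.98), Olfr1097 (-0.95), Olfr1014 (-0.94), Olfr775 (-0.83) and Olfr372 (0.72), each with a limma adjusted p of 0.999. S100a5 differed by 0.10 (SE 0.167) and Omp by -0.02 (SE 0.11). The Pcdh10 call ended when only the 2 groups compared entered the fit or when both pools numbered 4 were left out, with limma adjusted p up to 0.13 and values of 1.57 to 2.04 over all alternatives.

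Of the 26 gene lists in that comparison, the activity-raised genes were shifted upward (camera adjusted p = 0.000701), with 1 of 6 members passing, Pcdh10, which the axon sorting list also holds, and 5 of 6 with a positive difference. Without Pcdh10 the other 5 genes gave a camera p of 0.0473, not adjusted over the lists. The call was lost in camera at an estimated correlation (adjusted p = 0.127 with an estimated correlation). The number of lists called, 1, was 3 without undecanal pool 1 or vehicle pool 2 or 3, and 2 without undecanal pool 2 or vehicle pool 4. The lists of mature neurons (median -0.02, which turned positive with quantile normalization), immature neurons (-0.09), immediate early genes (-0.03) and aldehyde metabolism (-0.06) did not pass. Egr3 (-0.48) and Atf3 (0.30) had the smallest p among the immediate early genes, and Adh1 (-0.54) and Aldh1a2 (0.31) among the genes of aldehyde metabolism. Slc17a6 (0.21) and Rtp2 (-0.19) had the smallest p among mature neuron genes, and Olfr160 (0.36) and Olfr16 (0.26) among receptors with published ligands, none of which passed.

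In arrays titled GFP-, 2 odorant receptors were lower with undecanal when adjusted over the list alone. Olfr1095 fell by 1.83 on the log2 scale (SE 0.351, limma adjusted p = 0.0372), from a mean of 6.912 ± 0.278 (SD, n = 4) to 5.086 ± 0.969 (SD, n = 4), and was lower in 4 of 4 undecanal arrays than in every vehicle array. Olfr1535 fell by 1.08 (SE 0.189, limma adjusted p = 0.0264), from 4.233 to 3.155, with both means below the background level of 4.802. Neither passed over all genes, where 0 probe sets passed in limma and 914 had an unadjusted p under 0.05 against 1110 by chance; 68 receptors did against 54.55. Pcdh10 was 1.35 higher (SE 0.218, limma adjusted p = 0.179) with no overlap between groups, but did not pass over all genes, and was the 1 of 6 activity-raised genes that passed when adjusted over the list alone. Of all tested probe sets, 2.2% had no overlap between the groups and 2.86% would by chance. The other named genes with the smallest p also did not pass, the adhesion receptor Cd44 (2.45), Cd14 (0.90), Ugt2a3 (0.74) and Opn1sw (-0.67), each with at least 1 group mean below background.

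Olfr1095 did not pass without undecanal pool 1 or 2 or vehicle pool 2, 3 or 4, with limma adjusted p over all alternatives from 0.00655 to 0.303, nor did Olfr1535 without undecanal or vehicle pool 3 or 4 or with arrays centred on the receptor median (0.0121 to 0.315). With that centring the count stayed 2, but 1 receptor was higher and 1 lower. The receptor count in arrays titled GFP- was 0 without vehicle pool 3 or 4, 1 without undecanal pool 1 or 3 or vehicle pool 2, and 4 without vehicle pool 1. The odorant receptors as a list were shifted down (median -0.09, camera adjusted p = 0.00808), a call lost without undecanal pool 3 or 4 or vehicle pool 1 or 2 and with an estimated correlation (adjusted p = 0.957 with an estimated correlation). S100a5 differed by 0.16 (SE 0.167) and Omp by 0.02 (SE 0.11). The immediate early genes (median 0.20, camera adjusted p = 0.305), the activity-raised genes (0.12, camera adjusted p = 0.13) and the mature neuron list (-0.04) did not pass. Among activity-raised genes Lrrc3b (0.43) came after Pcdh10 by p and did not pass. Nr4a3 (0.79), Nr4a2 (0.64), Cngb1 (0.36), Rtp1 (-0.19), Aldh9a1 (-0.30), Aox1 (-0.26), Olfr2 (-0.40) and Olfr16 (-0.31) had the smallest p in their lists and did not pass. In vehicle arrays titled GFP- Nr4a3 lay below background, from 2.84 to 4.034.

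The interaction asked whether the difference between sort fractions changed with undecanal. 1 of 1091 receptors passed when adjusted over the list alone, Olfr1535, with a difference of 1.49 (SE 0.267, limma adjusted p = 0.0348), but its group means lay between 3.155 and 4.233, under the background level. With arrays centred on the receptor median Olfr1535 did not pass and another receptor did, with a negative difference. With the pool as a replicate block the count was 0, as it was without undecanal pool 3 or 4 or vehicle pool 1, 3 or 4. Over all genes 0 probe sets passed in limma and 584 had an unadjusted p under 0.05 where chance gives 1110, and 31 receptors did where chance gives 54.55. The 5 other genes with the smallest p were Cd44 (-2.32), Brwd1 (-1.14), B4galnt2 (-1.04), Nat8f6 (-0.999) and Slc12a3 (-0.92), each with a limma adjusted p of 1. All group means of B4galnt2, Nat8f6 and Slc12a3 lay below background, as did that of Cd44 in vehicle arrays titled GFP-. The undecanal effect on Pcdh10 was 0.56 larger in arrays titled GFP+ (SE 0.308, limma adjusted p = 1), so the fractions were not shown to differ in it. S100a5 differed by -0.06 (SE 0.237) and Omp by -0.04 (SE 0.155). No list passed in camera, and those with the smallest adjusted p were the ensheathing glia (median -0.46) and the trace amine-associated receptors (0.42), both at 0.0769. With 1 pool left out, 4 lists passed without undecanal pool 1, 3 without vehicle pool 3, and 1 without undecanal pool 2 or vehicle pool 2 or 4.

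Between the sort fractions of vehicle pools, the largest differences outside the receptors were in genes known from neutrophils and monocytes, higher in arrays titled GFP+. Lcn2 was 11.3 higher on the log2 scale (SE 0.403, limma adjusted p = 2.08e-12), Ngp 10.9 (SE 0.461), Retnlg 10.3 (SE 0.195), Chil3 9.71 (SE 0.245), S100a9 9.33, S100a8 9.18, Lyz2 8.62, Mmp8 8.47 and Ly6c2 8.33. Each was higher in 4 of 4 vehicle pools and also in 4 of 4 undecanal pools, where Lcn2 differed by 11.5 and Ngp by 11.6. In arrays titled GFP-, Mmp8 and Ly6c2 lay below background with both agents, Chil3 with vehicle, and Retnlg, S100a8 and S100a9 with undecanal, so the size of these differences is limited by the floor. In all, 1959 probe sets were higher and 1138 lower in vehicle arrays titled GFP+, and 1960 higher and 969 lower in undecanal pools. That split depended on the scaling: with each array centred on its median it was 1570 and 11231 in vehicle pools, and 1584 and 11129 in undecanal pools. With quantile normalization it was 1876 and 1830, and 1869 and 1752, and with centring on the mature neuron list 3070 and 451, and 2792 and 437. The median difference of all probe sets was -0.113 in vehicle pools and moved to -0.469 with median centring, and values here are relative to the deposited scaling.

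Markers of several other cell types were also higher in arrays titled GFP+. In vehicle pools 13 of 14 immune genes were higher (camera adjusted p = 1.73e-23), 10 of 10 microvillar cell genes (1.58e-14, such as Foxi1 4.11, Cftr 3.61 and Trpm5 3.54) and both measured erythroid genes (Slc4a1 3.11, Alas2 2.49). Genes of immature neurons were higher in 11 of 14 cases (camera adjusted p = 2.27e-14), such as Gng8 (4.39), Dpysl3 (3.94) and Tex15 (3.80), and those of basal progenitors and the cell cycle in 12 of 14 (1.80e-15), such as Mki67 (5.11) and Nhlh1 (4.49). Of the immediate early genes 14 of 19 were higher (camera adjusted p = 2.28e-18), led by Egr2 (6.62), Egr1 (6.02), Btg2 (5.93) and Fosb (4.87). The Bowman gland list was higher in 4 of 8 genes (camera adjusted p = 5.98e-06), led by Ltf (7.65), which neutrophils also express, and Sox9 (3.82). The list of guanylate cyclase D neurons was higher in 6 of 10 (camera adjusted p = 8.40e-06), with Pde2a (3.43) and Ms4a4c (2.66), a family also expressed by immune cells. The activity-raised genes were lower in 5 of 6 (camera adjusted p = 5.80e-05). All of these list calls held with an estimated correlation, in vehicle and in undecanal pools.

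Mature neuron genes were lower in 4 of 19 (Pde1c -0.65, Slc24a4 -0.60, Ano2 -0.51, Faim2 -0.41), with a median of -0.23. Centring arrays on that list sets its mean difference to 0, so that setting does not test its members. The call of Slc24a4 was lost without vehicle pool 1, and that of Faim2 with the pool as a replicate block (limma adjusted p = 0.0525) and without vehicle pool 1, 3 or 4 or undecanal pool 2 or 3, among others. Their camera adjusted p of 0.00762 in vehicle pools was 0.311 with an estimated correlation. Sustentacular cell genes were higher in 5 of 12 (Cyp1a2 2.72, Sult1c1 2.52), and the list passed as higher (camera adjusted p = 8.18e-06). That call was lost in 1 of 13 alternatives, the estimated correlation (camera adjusted p = 0.217). Genes of aldehyde metabolism were higher in 4 of 20 (Aldh2 3.49, Aldh9a1 1.70; camera adjusted p = 0.0362, and adjusted p = 0.417 with an estimated correlation), a call lost without vehicle pool 3; their median of 0.03 turned to -0.32 with median centring. Vomeronasal and bitter receptors, which serve as the background family, had a median of -0.28 and passed as lower (camera adjusted p = 0.000805). Of these 356 probe sets 17 were called lower and 1 higher. The list call was lost with an estimated correlation (camera adjusted p = 0.217), and with mature neuron list centring the median was -0.0179. Small negative medians in this comparison may therefore reflect the scaling, which was not tested. In vehicle pools the lists of ciliated cells (median -0.38), sex-linked genes (-0.32), receptors with published ligands (0.57), odorant receptors (-0.37) and trace amine receptors (-0.74) did not pass in camera, which tests a shift in 1 direction, though many single receptors passed both ways. Nor did horizontal basal cells (0.02), ensheathing glia (0.15), vascular cells (-0.15), axon sorting (-0.14), heat shock (0.29), unfolded protein response (-0.14), receptor choice (-0.04) and oxidative phosphorylation (-0.15), whose medians changed sign with median or mature neuron list centring or, for receptor choice, also with quantile normalization. Single members of these lists passed in vehicle pools, among them Itga6 (1.48), Deup1 (-1.63), Dcn (1.26), Epha5 (-0.85) and Lbr (1.07). The call of Deup1 was lost without vehicle pool 3, that of Dcn without both pools numbered 4 and that of Epha5 with mature neuron list centring. In undecanal pools 13 of 26 lists passed, as in vehicle pools, and 9 with an estimated correlation.

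**Figure D2:**
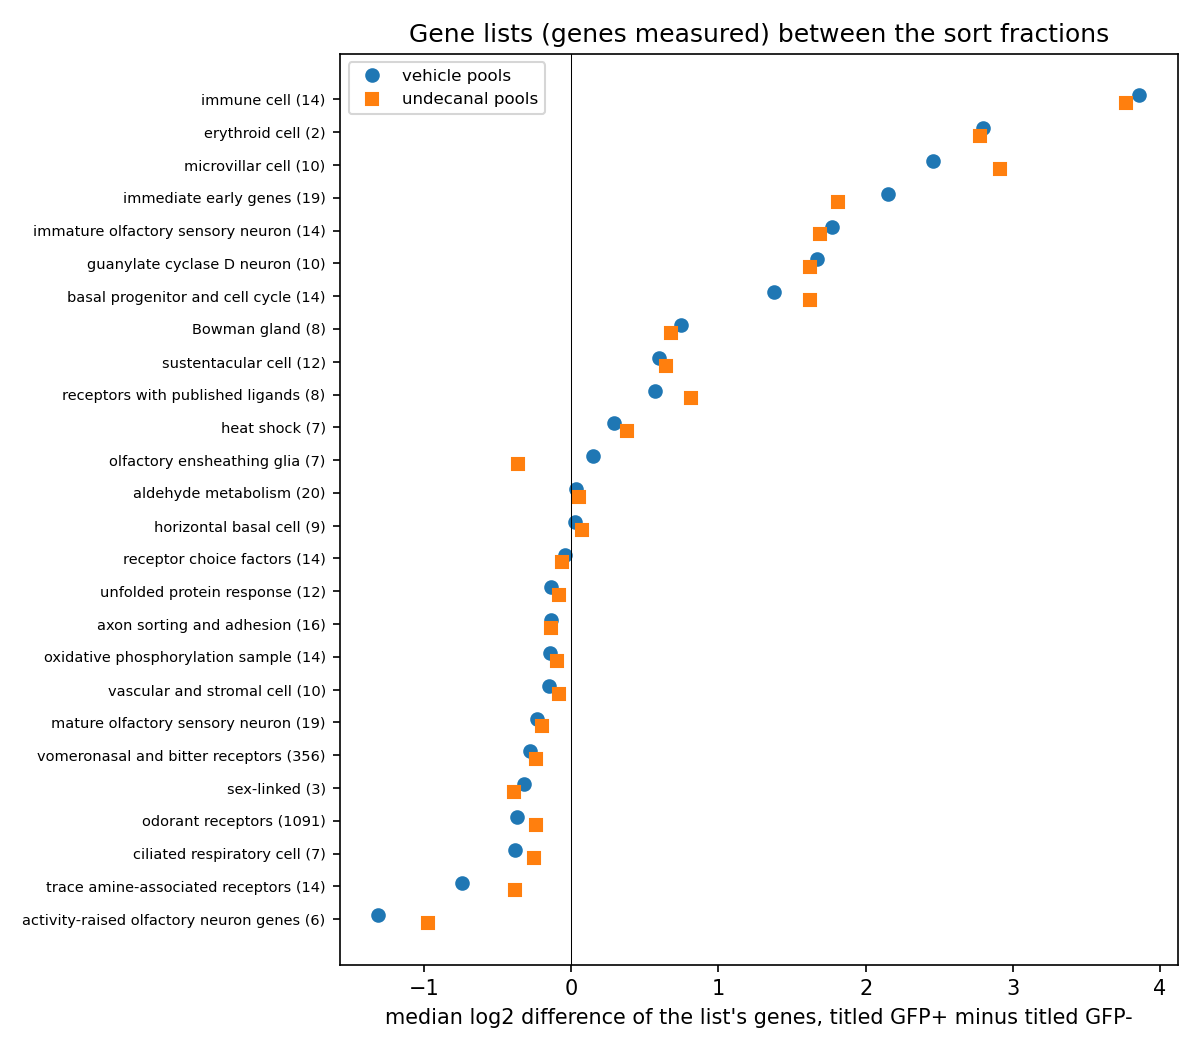
Median log2 difference, titled GFP+ minus titled GFP-, over the measured genes of each list, in vehicle pools (blue circles) and undecanal pools (orange squares), with the number of genes in parentheses. Immune cell genes had the highest median, 3.86 and 3.77, and activity-raised genes the lowest, -1.31 and -0.97.

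Odorant receptors differed in both directions between the fractions. In vehicle pools 285 receptors were higher and 447 lower in arrays titled GFP+, adjusted over the list alone in limma, and 247 and 394 when adjusted over all genes. The lean to lower receptors depended on the scaling. Of the called receptors 38.9% were higher, against 30.1% with median centring and 46.8% with mature neuron list centring. In undecanal pools the counts were 317 and 427, and 264 and 367. The highest were Olfr1507 (8.35, SE 0.284, limma adjusted p = 4.20e-13), Olfr1213 (8.29), Olfr390 (7.45), Olfr1384 (7.09) and Olfr1178 (7.04), with Olfr1178 below background in both groups titled GFP-, which limits the size it could show, and in undecanal pools these differed by 8.67, 7.59, 7.26, 6.79 and 6.54. The lowest were Olfr1093 (-5.71), Olfr110 (-5.47), Olfr309 (-5.32), Olfr536 (-5.30) and Olfr372 (-5.15), followed by Olfr481, Olfr533, Olfr494, Olfr472 and Olfr613, from -5.04 to -4.21. In arrays titled GFP+ the mean of Olfr1093 with vehicle and both means of Olfr613 lay below background, so the size and rank of these differences are set by the floor. Across the 1091 receptors the 2 sets of differences, which share no array, correlated with r = 0.983 and rho = 0.974, though genes are not independent replicates. Among receptors with published ligands, Olfr1440 (3.46) and Olfr16 (1.64) were higher and Olfr160 (-3.18) and Olfr15 (-2.40) lower in vehicle arrays titled GFP+.

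**Figure D3:**
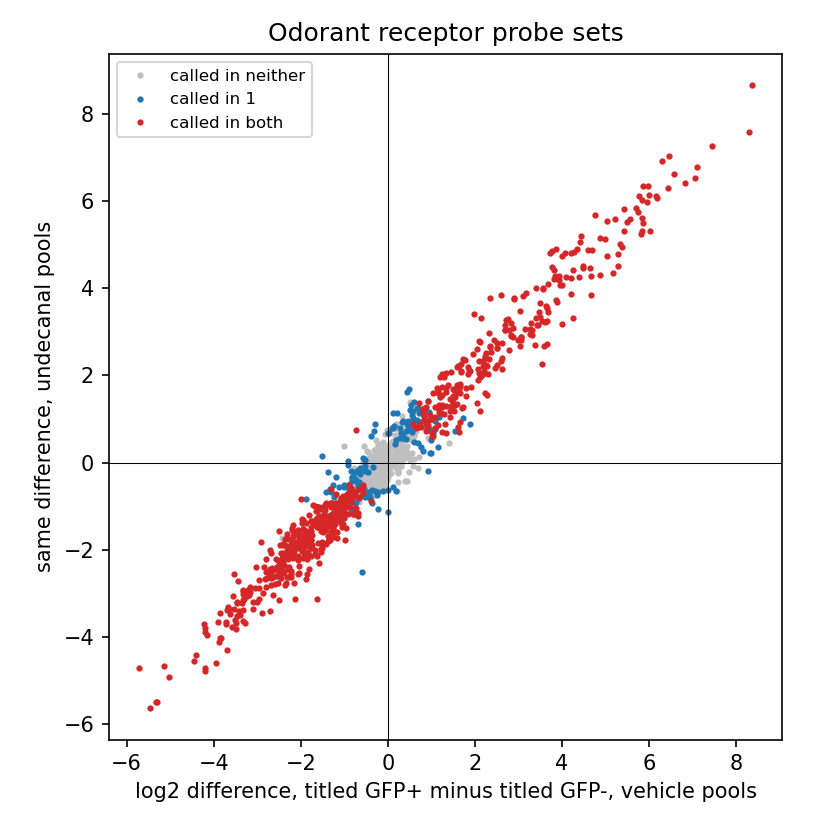
Log2 difference, titled GFP+ minus titled GFP-, of each of 1091 odorant receptor probe sets in vehicle pools (x axis) against undecanal pools (y axis), coloured by whether limma called it in neither, in 1 or in both. The points follow a line (r = 0.983), and 669 receptors were called in both with the same direction.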

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

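All tests of explanations in this part were chosen after the result was seen.

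S100a5 was lower in the array titled GFP+ of 8 of 8 pools, with differences from -1.32 to -0.705 on the log2 scale (exact two-sided sign-flip permutation p = 0.00781, the smallest 8 pools can give). A lower share of neurons alone would lower neuronal genes alike. The activity-raised list, which holds S100a5 itself, fell further than the mature neuron list in 8 of 8 pools, by a mean of -0.994 (SD 0.155). That argues against a lower share as the only cause. Mature neuron probe sets are bright, and whether their signal was compressed was not tested, so a lower share is not excluded. The titles may carry the GFP sign of the other fraction, or S100a5 mRNA and the sorted GFP may differ biologically, which was not tested. The other 5 activity-raised genes also fell against the mature neuron list in 8 of 8 arrays titled GFP+, by a mean of -1.05 (SD 0.191), as exchanged titles would need. The immediate early genes, which activity raises too, rose against it in 8 of 8, by a mean of 2.79 (SD 0.39), as the titles would have it, though markers of immune and progenitor cells rose there as well. Of 14 immune genes 13 were higher in arrays titled GFP+, as were both measured erythroid genes. Their list medians were 3.86 and 2.8 in vehicle pools and 3.77 and 2.78 in undecanal pools. GFP driven from S100a5 in neurons would leave such cells in the other fraction. These values argue against the titles as they stand, though the sort itself was not examined.

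Pcdh10 was higher with undecanal in both fractions. The male share of the pools does not account for it, since with the mean of Y-linked genes as a covariate the smaller effect was 1.35 (SE 0.224) and the other 1.91. A rise of all activity genes as large as that of Pcdh10 does not either, since the mean of the other 5 activity-raised genes differed by 0.272 (SE 0.248) at most. A smaller general rise is not excluded, and in titled GFP+ these 5 genes gave a camera p of 0.0473, not adjusted over the lists. A response to undecanal stays open as a hypothesis.

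Receptors differed both ways between the fractions. More non-neuronal RNA in arrays titled GFP+ would lower receptors together, yet 38.9% of called receptors were higher in vehicle pools and at least 30.1% under every scaling. Noise of single probe sets does not account for it, since r between vehicle and undecanal pools was 0.983. A difference in activity between neurons of different receptors stays open as a hypothesis, and shared signal of paralogs was not tested here.

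Counts of calls were compared with all 35 splits of the 8 arrays, or of the 8 pools for the interaction. Chance is not excluded for the counts with undecanal above 0. For receptors in titled GFP- 11 splits gave at least the real 2, with up to 99, and in the interaction 6 gave at least the real 1, with up to 6. Over all genes in titled GFP+ 4 splits gave at least the real 1, with up to 104, which concerns the number of calls and not Pcdh10 itself. Where the real count was 0, all 35 splits reach it by definition and the comparison says nothing about chance; the other splits gave up to 14 receptors in titled GFP+, and over all genes up to 3 in titled GFP- and 31 in the interaction. The highest counts of 14, 99 and 6 receptors and of 104 and 31 probe sets all came from 1 split, pools numbered 1 and 2 of both agents against those numbered 3 and 4. They point to a structure that follows the pool number across agents, so the 35 splits are not free of other differences. The mean of the sex-linked list ran along it in both agents and fractions, from 8.996 to 9.563 in pools 1 and 2, 8.496 to 8.797 in pools 3 and 6.378 to 7.617 in pools 4, but whether the sex of the mice is its source was not tested. Among the 8 splits with 1 pool of each number on either side, too few for a share under 5%, the others gave at most 0 against the real 2, 1 and 1. With the number as a replicate block these 3 counts stayed the same, with Pcdh10 still called in titled GFP+. Between fractions 1 of 35 splits, the real one, was as large in each case. In vehicle pools 732 receptors stood against at most 91 and 3097 probe sets against at most 1. In undecanal pools 744 stood against at most 1 and 2929 against at most 2. Every other split mixes the fractions on both sides, which widens the spread within groups and keeps its counts low. Among the 8 splits that part every pool, the others gave at most 0 receptors, and at most 0 and 2 probe sets. With the fractions paired by pool, 8 splits are too few for a share under 5%, so these splits do not exclude chance. For the receptors other values argue against it. Over 1091 receptors the differences of vehicle and undecanal pools, which share no array, correlated with r = 0.983, and 669 of 670 called in both had the same direction.

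Olfr1535 was the 1 receptor whose undecanal effect differed between the fractions in a test of the difference, by 1.49, with all group means below background. The call was lost with the pool as a replicate block (limma adjusted p = 0.222) and with arrays centred on the receptor median (limma adjusted p = 0.143), where another receptor passed instead.

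Single arrays stood apart from the other 3 of their group in 29 of 508 groups examined, where chance gives 25.4. In vehicle arrays titled GFP- these were Ano2 (17.26), Dcn (5.194), Omp (18.71) and Olfr1178 (3.55) in pool 2, Deup1 (5.969), Faim2 (17.64) and Nr4a3 (4.034) in pool 4, Egr2 (4.978) in pool 3, and Gng8 (6.918), Rtp2 (15.62) and the array median (5.974) in pool 1. In vehicle arrays titled GFP+ they were Chil3 (14.07) and Lcn2 (16.14) in pool 4, Olfr1213 (12.47) and Rtp1 (16.97) in pool 1, Olfr372 (5.562) and the array median (6.265) in pool 3, and Vmn1r143 (2.656) in pool 2. In undecanal arrays titled GFP+ they were Cngb1 (3.983) and Dpysl3 (12.45) in pool 2, Cyp2f2 (13.26) and Sult1c1 (11.94) in pool 1, Olfr1 (8.573) in pool 3, and Olfr613 (4.991) and S100a8 (13.2) in pool 4. In undecanal arrays titled GFP- they were Epha5 (10.77) and Olfr15 (14.1) in pool 1, and Olfr1384 (5.22) and Olfr160 (11.76) in pool 4.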

How the results depend on the processing

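The fits with receptors alone, without both pools numbered 4 and of gene lists with the replicate block were chosen after the data were seen. Of 4751 values of named genes under alternatives, 4560 kept their direction and side of the threshold and 175 lost the call. Another 2 gained one (Omp between fractions of either agent, with median centring), and 14 turned sign. Many of these values belong to results not called in the main fit, which could not lose a call. Counted by result, 35 of 218 lost the call in at least 1 alternative. The 14 that turned sign were all of Omp or S100a5 near 0, and the cause was not tested. Omp with undecanal in titled GFP+ was 0.0563 with quantile normalization and 0.00441 without both pools numbered 4, and from -0.0186 to 0.0425 in titled GFP- with 1 pool left out. Its interaction was 0.0317 with quantile normalization and -0.0651 to 0.00188 with 1 pool left out, and that of S100a5 -0.182 to 0.0618. Between fractions Omp was 0.255 and 0.194 with centring on the mature neuron list, which holds it, 0.00286 without both pools numbered 4, and -0.0479 to 0.019 in vehicle pools with 1 pool left out.

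The 1 probe set called with undecanal in titled GFP+ became 0 in a fit of only the groups compared and without both pools numbered 4. The 1 receptor of the interaction became 0 with the replicate block by pool, quantile normalization, the filter above background families, the filter above the 25th percentile, adjustment over all probe sets, receptors alone in the fit (with or without the replicate block) and without both pools numbered 4, and was 0 to 1 with 1 pool left out. With receptor median centring the count stayed 1, but Olfr1535 no longer passed. The 2 receptors in titled GFP- became 4 with a prior variance trend, 1 with quantile normalization or mature neuron list centring, 2 with receptor median centring but without Olfr1535 and with 1 higher and 1 lower, and 0 with either filter, only the groups compared, adjustment over all probe sets, receptors alone (with or without the block) and without both pools numbered 4, and were 0 to 4 with 1 pool left out. Fewer arrays or a wider adjustment were part of several of these settings, and otherwise the cause was not tested. Calls between fractions became 12801 in vehicle and 12713 in undecanal pools with median centring, which subtracts medians that are higher in arrays titled GFP+; 2707 and 2550 of the main calls were shared with the same direction. Gene lists called with undecanal were 0 with an estimated correlation and with fry in both fractions, against 1 each; with 1 pool left out they were 1 to 3 in titled GFP+, 0 to 2 in titled GFP- and 0 to 4 in the interaction. The replicate block by pool gave 3503 and 3259 calls between fractions against 3097 and 2929, and among named genes ended the calls of Faim2 and Vmn1r143 in vehicle and Slc24a4 in undecanal pools. With 1 pool left out, calls between fractions fell to as few as 2298 in vehicle pools (without vehicle pool 1) and 2187 in undecanal pools (without undecanal pool 1). Probe sets near the background level of 4.802 limit what dim receptors can show.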

Other observations

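The split into receptor classes and the choice of Taar genes beyond Taar2, Taar7a, Taar4 and Taar9 among the tests in this part came only after values were seen. Trace amine-associated receptors, a small family of olfactory receptors for amines, also split between the fractions. In vehicle pools Taar2 (3.32), Taar7a (1.88), Taar6 (1.77) and Taar7f (1.67) were higher in arrays titled GFP+, and Taar4 (-2.85), Taar9 (-2.07) and Taar3 (-1.75) lower, all passing in limma. In undecanal pools the same receptors differed by 4.10, 2.50, 2.09, 2.05, -2.54, -2.56 and -2.01. Of 14 measured, 11 passed in vehicle pools, these 7 with Taar7d (0.92) higher and Taar5 (-1.54), Taar7b (-1.36) and Taar8a (-1.30) lower. In undecanal pools Taar7d (1.45) passed again and Taar7e (-0.84) passed, whereas Taar5 (-0.73, limma adjusted p = 0.211), Taar7b (-0.90, 0.0887) and Taar8a (-0.76, 0.133) did not. By the MOR numbers among their synonyms, 121 class I and 950 class II receptors had similar medians between fractions in vehicle pools, -0.37 for both, with 20 and 258 higher and 41 and 399 lower. The camera test of the class difference gave p = 0.99, and p = 0.997 with an estimated correlation.

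3 hypotheses were tested with predictions written before their results were seen. Undecanal may move neurons of a receptor from one gate to the other, in which case receptors that rise in one fraction fall in the other; r across 1091 receptors between the effects in both fractions was 0.206, and 9 of 35 pool splits gave a value as low. The prediction of a value below 0 was wrong, since both fractions come from the same pools and the other 34 splits gave 0.125 to 0.37, so the test neither supports nor excludes it. Receptors of 1 MOR family may share their undecanal response in arrays titled GFP-. The share of variance between 160 families was 0.0592, and 33 of 35 splits gave as much, so the prediction was not met. The other splits gave 0.0232 to 0.228 and are not free of differences that follow the pool number, so the test does not exclude the hypothesis. Receptors of 1 family may share their difference between fractions; the share was 0.178 in vehicle pools, above all 1000 shuffles of the family names, whose highest was 0.0756. Signal shared between close paralogs would raise that share too and was not told apart from it by a test.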
